A study of Mus musculus with 2 samples.

How the data were processed

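Single-cell RNA sequencing was done on live Citrine-positive cells sorted from the decidua and the myometrium of female Il33cit/wt dams mated with C57BL6 studs, on day 7.5 of pregnancy, with 1 library per tissue. Per the labels, tissues were digested with collagenase A and DNase I, dead cells were excluded with DAPI, a C57BL6 mouse set the Citrine gate, and libraries were made with the 10x Chromium 3′ chemistry. The submitters' processing notes list bcl2fastq 2.20.0.422, Cell Ranger 6.1.0 and genome build mm10, without the annotation release or parameters. The deposited decidua matrix holds raw UMI counts, not normalised, for 31053 genes and 2128 barcodes in 9792580 entries, which was checked on the values. For the myometrium the number of barcodes (15046) was used and the counts were not analysed here. The same 31053 features were listed for both libraries, and 0 of them was a reporter feature. Of the gene identifiers, 99.6% were matched to the GENCODE M21 mouse annotation (GRCm38), from which gene positions were taken. Identifiers that share a symbol (35 symbols, 2 of them in a readout list) were summed.

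Cells with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept. Of the 2128 barcodes, 424 (19.9%) failed: 128 were over the mitochondrial limit and 296 others were under the gene or UMI minimum. Scrublet, run through scanpy 1.11.5 with an expected rate of 2%, called 7 of the 1704 remaining cells doublets (0.411%), which were left out. The 1697 kept cells had 1019 to 173130 UMIs each. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were taken among those in at least 3 cells, with every readout-list gene, Il33 included, left out, so that no readout gene defined a cluster. Genes that vary with readout genes, such as other cell cycle genes, stayed eligible. Scaled values were limited to 10, and 30 principal components, 15 neighbours, a shared-neighbour graph of pairs with a Jaccard index of at least 0.0667, and Leiden clustering at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9, seed 0) gave 10 clusters. Other tools were Python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

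Before the data were examined, 22 marker lists (153 genes), 14 readout lists (208 genes), the rule for named genes, the comparisons and most alternatives were fixed. A cluster took the name of the marker list with the largest share of members at 50 UMIs per 1000000 UMIs (CPM) or more, with ties broken by the number of such markers and then by their mean level. It stayed unnamed with fewer than 3 such markers, or when its median depth was under the median of all kept cells divided by 3 and none of its 10 leading genes was in that list. Leading genes are those with the highest ratios among genes at 100 CPM or more, and they describe identity. Clusters with the same name formed a class, written with the ending -like. The marker lists covered decidualised stroma, stromal and adventitial fibroblasts, smooth muscle, pericytes, blood and lymphatic endothelium, epithelium, mesothelium, trophoblast, endoderm or embryo, natural killer cells, group 2 innate lymphoid cells, T cells, B cells, macrophages or monocytes, dendritic cells, neutrophils, mast cells, erythroid cells, platelets and Schwann cells.

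For each class of at least 20 cells, UMIs were summed and compared, as CPM, with the sum of all other kept cells. Each cluster of the most abundant class was compared with the other cells of that class. Levels carry exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, at 95%. With 1 library there are no replicates, so a fixed size rule was used in place of a test: a gene was higher at a ratio of at least 2 and lower at a ratio of at most 0.5. A sum of 0 was set to a floor of 3 counts over the group when a ratio was formed, and a bound on the wrong side of 1 was set to 1. List members with at least 50 UMIs over the kept cells were measured (189 of the readout genes, among 13276 genes in all). The median log2 ratio of each list was placed among those of 10000 random lists drawn from 20 expression bins, as a description. Named genes were Il33, Il1rl1 and Il1rap, and the readout genes at 100 CPM or more in either group that passed the size rule, up to 25 per class and 15 per cluster by absolute log2 ratio. Genes of the lists named outside this rule were chosen after their values were seen. So was the comparison of clusters 2 and 8, and the division of cluster 2 into subclusters, which are the parts of cluster 2 in a clustering of all kept cells at resolution 1.

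Alternatives were mitochondrial limits of 10% and 25%, stricter and no cell filters, doublets kept, resolutions of 0.25 and 1, 4000 variable genes, 15 principal components, readout genes allowed among the variable genes, another seed, thinning to 5000 and 2000 UMIs per cell, means over cells, and scaling without mitochondrial genes and the 20 most abundant genes. Thinning to 20000 UMIs and a minimum of 5000 UMIs per cell were added after seeing the data. The procedure was tested on simulated data only, so the rates that follow need not hold for the intervals, size rule and percentiles in the real cells. Of the real cells, 34 held at least 3 Il33 UMIs, against 8.89 from Poisson sampling of 1 equal level per class. Intervals that cover counting error only can therefore be too narrow there. Clustering of cells drawn from 5 class profiles gave 5 clusters with an adjusted Rand index of 0.978. With 200 of 13276 genes changed, the intervals covered the true ratio for 95.3% to 96.9% of genes. A 3-fold higher level passed the size rule in 94% to 100% of genes. A 3-fold lower level passed in 100% for the endothelial-like class, 96% for the stromal class and 92% for the epithelial-like class, and in 80% for the natural killer cell-like class and 72% for cluster 8. Unchanged genes passed it in 0.0841% for the endothelial-like class and up to 6.81% for cluster 8, but in 0% of genes at 100 CPM or more. Of 100 unchanged lists, 7 fell outside the percentiles from 2.5 to 97.5, and of 100 lists raised 1.5-fold, 100 were above them.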

Results

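Live cells carrying Citrine, a fluorescent reporter placed in 1 allele of Il33, were sorted from the uterus of pregnant reporter mice on day 7.5 of pregnancy, and their transcripts were counted by droplet single-cell RNA sequencing. Il33 encodes interleukin-33, a nuclear alarmin of the IL-1 family that acts on leukocytes through the receptor chain ST2. The series asks which subsets of reporter-positive cells are present in the decidua, the uterine lining remodelled around the implanted embryo, and in the myometrium, the muscle wall. There was 1 library per tissue. The decidua library held 2128 barcodes and 71139632 unique molecular identifiers (UMIs), from 500 to 173130 per barcode with a median of 29589. The myometrium library listed 15046 barcodes, 7.07 times as many, and its counts were not analysed here, so the tissues were not compared. After filtering, 1697 decidual cells with 70077806 UMIs were kept, with medians of 37851 UMIs and 5750 genes per cell. Cells of 1 library are not replicates, so no p-value is given. Ranges in parentheses are exact 95% intervals that cover counting error only, not the spread between animals.

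The reporter-positive decidual cells were mostly blood endothelial-like, with a second large group of stromal fibroblast-like cells. Blood endothelial-like cells numbered 1107, a share of 65.2% (62.9 to 67.5), and made up 6 of the 10 clusters, each with 9 of 9 endothelial markers detected. Stromal fibroblast-like cells numbered 436, or 25.7% (23.6 to 27.8), and formed cluster 2, whose leading genes included Tdo2, a tryptophan-degrading enzyme, the tachykinin gene Tac2, the chemokine gene Cxcl14 and the WNT ligand gene Wnt6. Epithelial-like cells (cluster 7) numbered 56, or 3.30% (2.5 to 4.26), and were led by Serpina1e, Prap1, the tight junction gene Cldn4 and the protease gene Mmp7. Natural killer cell-like cells (cluster 9) numbered 43, or 2.53% (1.84 to 3.40), and were led by Prf1, which encodes perforin, and by granzyme genes such as Gzmd, Gzmc and Gzmf; their share was between 1.14% and 14.6% over the alternative settings, the latter with no filter. Cluster 8 held 55 cells, or 3.24% (2.45 to 4.20), and was left unnamed. The stromal fibroblast (9 of 9 markers detected) and mesothelial (5 of 5) lists tied there, and the tie was broken for the longer list. Also detected were 5 of 6 adventitial fibroblast, 4 of 9 decidualised stromal, 5 of 9 blood endothelial and 3 of 8 epithelial markers. None of the stromal fibroblast markers was among its 10 leading genes, which was also true of cluster 2, so depth decided that it stayed unnamed. Its median depth of 12392 UMIs was just under the limit, the median of all kept cells (37851) divided by 3. Its leading genes were Upk3b, a mesothelial marker, Dpt and Clec3b, markers of adventitial fibroblasts, and Hpgd, a prostaglandin-degrading enzyme. Single cells with at least 3 mesothelial markers numbered 9 of its 55, and under 4 alternative settings a separate mesothelial-like class of 9 cells formed. Under 8 alternative settings, 1 of them added after seeing the data, the stromal share was between 28.3% and 29.2%, with most or all cells of cluster 8 in that class; with no filter all 55 were also there, at a share of 24.2%.

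**Figure D1:**
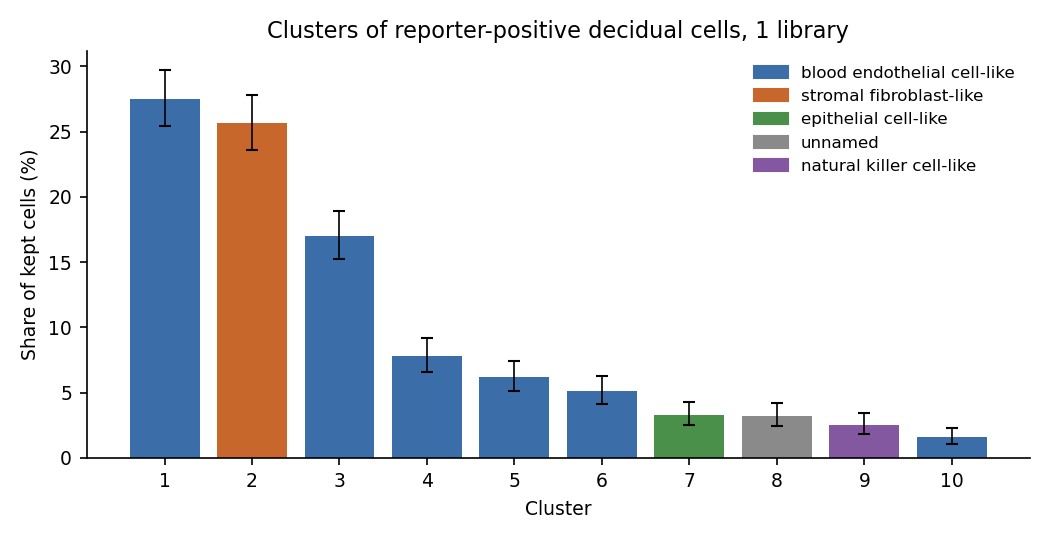
Share of the 1697 kept decidual cells (%, vertical axis) in each of the 10 clusters (horizontal axis), with bars coloured by class and error bars showing exact binomial 95% intervals. The largest are cluster 1, blood endothelial-like, at 27.5%, and cluster 2, stromal fibroblast-like, at 25.7%.

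Transcripts of endothelial and stromal markers were also the most widely detected when single cells with a UMI for at least 3 markers of a list were counted, a count of detection that does not name the cell. Such cells numbered 1216 (71.7%) for blood endothelium, 510 (30.1%) for stromal fibroblasts, 610 (35.9%) for decidualised stroma, 441 (26.0%) for adventitial fibroblasts and 212 (12.5%) for epithelium, and a cell could count for more than 1 list. Of the 212 cells with epithelial markers, 145 were in the stromal fibroblast-like class and 56 in the epithelial-like class, and of the 510 with stromal fibroblast markers 433 were in the stromal fibroblast-like class. For decidualised stroma the share was 87.4% of stromal fibroblast-like but also 15.4% of blood endothelial-like and 33.9% of epithelial-like cells, so its markers were not confined to stromal cells. There were 86 (5.07%) for smooth muscle, 28 (1.65%) for macrophages or monocytes, 26 (1.53%) for natural killer cells and 22 (1.30%) for endoderm or embryo. Pericyte markers marked 14 cells (0.825%), mesothelial and B cell markers 9 each (0.530%), lymphatic endothelial markers 8 (0.471%), group 2 innate lymphoid markers 3 (0.177%), T cell markers 2 (0.118%) and platelet markers 1 (0.0589%). For trophoblast, dendritic cells, neutrophils, mast cells, erythroid cells and Schwann cells the count was 0 of 1697 cells, which allows up to 0.177% of cells with such UMIs by a limit of 3 counts (exact interval 0 to 0.217) and sets no limit on cells of these types. The mast cell list had 2018 UMIs in the kept cells, the dendritic cell list 758 and the neutrophil list 96. In endothelial-like clusters 5 and 10 the mast cell list UMIs, 64 and 11, were all of Kit, so they need not come from mast cells. They are a small part of the 2018 and do not settle the source of the rest. Cluster 9 was mixed: 26 of its 43 cells held at least 3 UMIs of natural killer cell markers, 11 held at least 3 of B cell but not of natural killer cell markers, and 5 held at least 3 of macrophage markers and of neither other list. In its summed counts 5 of 9 blood endothelial markers were also detected, among them Emcn at 206 CPM.

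Il33 transcripts were more abundant in stromal fibroblast-like than in blood endothelial-like and epithelial-like cells. The Il33 level there was 9.52 UMIs per 1000000 UMIs (CPM) (8.31 to 10.9), against 3.37 (2.83 to 3.98) in blood endothelial-like cells, a ratio of 2.82 (2.27 to 3.52). It was 0.558 (0.0676 to 2.02) in epithelial-like cells, from 2 UMIs. The stromal level was 17.1 times the epithelial level (4.67 to 142), and the endothelial level was 6.04 times the epithelial level (1.64 to 50.4). In cluster 8 it was 3.52 (0.726 to 10.3), from 3 UMIs, and in natural killer cell-like cells 0.780 (0.0198 to 4.35), from 1 UMI; neither interval separated these small classes from the endothelial level, and the ratio of the stromal level to that of cluster 8 was 2.71 (0.914 to 13.2), which holds 1. At least 1 Il33 UMI was found in 21.3% (17.6 to 25.5) of stromal fibroblast-like cells and 9.12% (7.49 to 11) of blood endothelial-like cells. The share in epithelial-like cells was 3.57% (0.435 to 12.3). Their median depth was 56072 UMIs, against 51325 in stromal and 30873 in endothelial cells. The endothelial share was not separable from the epithelial-like share by its interval. The latter rests on 56 cells, 2 of them with an Il33 UMI. After thinning the cells with at least 5000 UMIs to that depth, the shares were 3.70% (2.13 to 5.93) in stromal, 1.73% (1.04 to 2.68) in endothelial and 0% (0 to 6.85) in epithelial-like cells. This left out 3 stromal, 6 endothelial-like and 4 epithelial-like cells. Over all kept cells there were 367 Il33 UMIs in 200 cells, or 11.8% (10.3 to 13.4), and the 34 cells with at least 3 of them held 160, so the intervals understate the spread between cells.

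**Figure D2:**
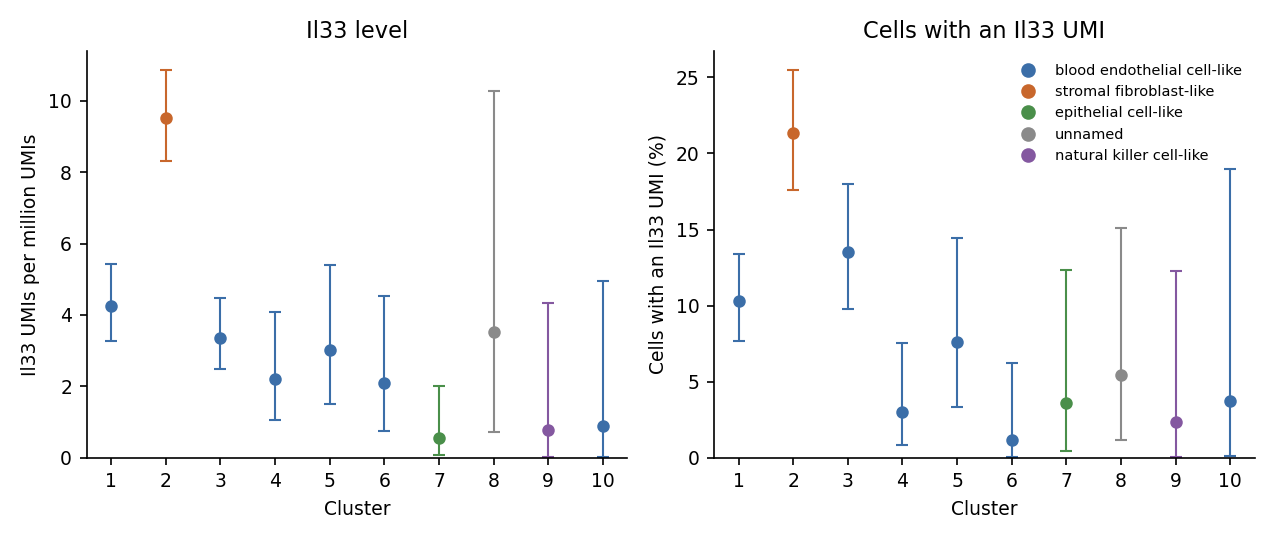
Il33 level in CPM (left, with exact Poisson 95% intervals) and percent of cells with at least 1 Il33 UMI (right, with exact binomial 95% intervals), by cluster (horizontal axes); points are coloured by class. Cluster 2, stromal fibroblast-like, has the highest points, at 9.52 CPM and 21.3% of cells, and its level interval overlaps that of cluster 8.

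The IL-33 receptor gene was at the limit of detection among the sorted cells, while the gene of its shared co-receptor had UMIs in each of the 5 classes. Il1rl1, which encodes ST2, had 1 UMI in all kept cells, in the epithelial-like class. Its level was 0 (0 to 0.0901 CPM) in endothelial-like and 0 (0 to 0.158) in stromal fibroblast-like cells. Il1rap, which encodes the accessory chain of several IL-1 family receptors, stood at 3.13 CPM (2.61 to 3.72) in endothelial-like cells, 2.22 (1.66 to 2.91) in stromal fibroblast-like cells and 2.51 (1.15 to 4.77) in epithelial-like cells. It was 5.86 (1.90 to 13.7) in cluster 8 and 3.90 (1.27 to 9.10) in natural killer cell-like cells. Il1rap UMIs per cell were 0.116 in endothelial-like, 0.119 in stromal, 0.161 in epithelial-like, 0.0909 in cluster 8 and 0.116 in natural killer cell-like cells. They differed little although the classes differed in depth, so free RNA in the droplets was not excluded as their source. On mouse build GRCm38 (mm10), the protein-coding gene Il33 (ENSMUSG00000024810) lies on the forward strand of chromosome 19 from 29925114 to 29960718. Il1rl1 (ENSMUSG00000026069) lies on chromosome 1 from 40429570 to 40465415, and Il1rap (ENSMUSG00000022514) on chromosome 16 from 26581704 to 26730117.

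In blood endothelial-like cells, set against the other kept cells, the interferon response and cytokine lists had the highest medians, and the prostaglandin and retinoid metabolism, complement, steroid hormone and chemokine lists the lowest. Of the 189 measured readout-list genes, 44 were at least 2-fold higher and 79 at least 2-fold lower. Of 10 measured interferon-response genes, 8 were higher and 0 lower, with a median log2 ratio of 1.55 (percentile 99.98 among 10000 random lists matched on expression). Examples are Bst2, a tethering factor for viruses, at 3.00-fold (2.93 to 3.07), and the ubiquitin-like modifier Isg15 at 2.84-fold (2.73 to 2.95). Cytokines acting on leukocytes had 5 of 11 members higher and 3 lower (median 0.95), including the stem cell factor gene Kitl at 14.0-fold (12.1 to 16.4) and Tgfb1 at 6.14-fold (5.76 to 6.55). Other higher genes were Ptgis, the prostacyclin synthase, at 17.0-fold (15.6 to 18.6), Nos3, the endothelial nitric oxide synthase, at 16.0-fold (13.0 to 20.1), and the semaphorin and VEGF co-receptor Nrp2 at 13.1-fold (11.5 to 15.1). The basement membrane collagens Col18a1 and Col4a2 were 7.10-fold (6.48 to 7.79) and 5.87-fold (5.59 to 6.16) higher, and B2m, the light chain of class I histocompatibility molecules, 4.74-fold (4.61 to 4.87). In the IL-1 family and alarmins, 1 of 9 members was higher and 5 were lower (median -1.22); the higher one was the alarmin gene Tslp, at 3.98 against 0.446 CPM.

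The lists with the lowest medians in endothelial-like cells were prostaglandin and retinoid metabolism (3 of 10 higher, 7 lower, median -3.79), complement and immune regulation (4 of 16 higher, 9 lower, median -2.24) and steroid hormone receptors and targets (2 of 12 higher, 8 lower, median -2.23). The retinoic acid-producing enzyme Aldh1a2 was 229-fold lower (155 to 354), the central complement gene C3 595-fold lower (289 to 1482) and the decidual transcription factor gene Hand2 174-fold lower (139 to 220). These ratios are to all other kept cells together: C3 stood at 22.4 CPM in stromal cluster 2 but at 1324 in cluster 8. Chemokines had 1 of 13 members higher and 8 lower (median -1.88), with Cxcl14 560-fold lower (490 to 644). The matrix list had 7 of 26 higher and 13 lower (median -0.92); the fibroblast collagen gene Col14a1 was 464-fold lower (289 to 797) and Col6a1 76.1-fold lower (63.9 to 91.4). Angiogenic factors had 4 of 16 higher and 8 lower (median -1.27), BMP and WNT signalling 5 of 17 and 8 (median -0.60), and decidual cell cycle regulators 1 of 10 and 4 (median -0.87). Glycolysis and hypoxia had 2 of 12 higher and 3 lower (median 0.17), proliferation 1 of 12 and 1 (median 0.44), and the dissociation and immediate early response 0 of 15 and 2 (median -0.47). The median of the complement list turned to 1.00 with a minimum of 1000 genes and 2000 UMIs per cell. Genes named in the class comparisons outside the fixed rule for named genes, such as Bst2, Isg15, Kitl, Nos3 and Tslp here, were chosen after their values were seen.

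In stromal fibroblast-like cells the steroid hormone, matrix and chemokine lists had the highest medians, and the cytokine, complement, IL-1 family and interferon response lists the lowest. Endothelial-like cells held 40938164 and stromal fibroblast-like cells 23420846 of the 70077806 kept UMIs, so each class made up most of the other's reference. Many differences in the endothelial-like and stromal comparisons are therefore the same contrast with opposite sign, and the comparisons are not independent of each other. The complement and IL-1 family medians were low in both, at -2.24 and -1.22 in endothelial-like and -1.79 and -1.42 in stromal cells. These lows do not stand for a difference between these classes. For example, H2-Aa had 77 UMIs in natural killer cell-like cells and 11 in all other kept cells. Of the 189 measured genes, 62 were higher and 66 lower. Steroid hormone receptors and targets had 8 of 12 members higher and 3 lower (median log2 ratio 1.70). Hand2, a progesterone target, was 142-fold higher (119 to 169), the progesterone receptor gene Pgr 12.7-fold (11.3 to 14.4) and the oestrogen receptor gene Esr1 3.48-fold (3.25 to 3.74). The matrix list had 13 of 26 higher and 7 lower (median 1.26), with Col14a1 at 45.3-fold (39.8 to 51.8), the fibronectin gene Fn1 at 25-fold (23.3 to 26.8) and the gelatinase gene Mmp2 at 11.6-fold (10.4 to 13.1), while Col18a1 was 10.8-fold lower (9.53 to 12.3). Both medians stood at percentile 100 among the matched random lists. Chemokines had 6 of 13 higher and 2 lower (median 0.72). Cxcl14 (ENSMUSG00000021508; chromosome 13, 56288643 to 56296551) reached 3619 CPM, 399-fold higher (363 to 440), and the monocyte attractant gene Ccl7 was 41.3-fold higher (24.2 to 76.4). BMP and WNT signalling had 8 of 17 higher and 5 lower (median 0.41), with Wnt6 at 300-fold (223 to 413), the WNT antagonist gene Sfrp1 at 74.9-fold (58.7 to 96.9) and Wnt5a at 38.0-fold (34.9 to 41.5).

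Angiogenic factors split evenly in stromal fibroblast-like cells, with 7 of 16 higher and 7 lower (median 0.37): Fgf2 was 74.2-fold (44.6 to 134) and Vegfa 12.2-fold (10.5 to 14.2) higher. Prostaglandin and retinoid metabolism also split, 5 of 10 higher and 5 lower (median 0.02), with Ptges, a prostaglandin E synthase, at 59.5-fold (41.8 to 87.4) and Aldh1a2 at 40.1-fold (34.7 to 46.6), and Ptgis 26.2-fold lower (23.0 to 29.9). The interferon response had 0 of 10 higher and 7 lower (median -1.42; Bst2 2.51-fold lower, 2.45 to 2.57). Complement and immune regulation had 5 of 16 higher and 11 lower (median -1.79). Its higher genes included the complement inhibitor gene Cd55 at 10.5-fold (9.94 to 11.2), and its lower ones the class I genes H2-D1 and B2m, 7.76-fold (7.48 to 8.06) and 6.02-fold (5.82 to 6.23). Cytokines acting on leukocytes had 2 of 11 higher and 6 lower (median -2.11; Tgfb1 7.74-fold lower, 7.14 to 8.41), and the IL-1 family 1 of 9 higher, Il33 itself, and 5 lower (median -1.42). Decidual cell cycle regulators had 3 of 10 higher and 3 lower (median 0.22), among them the inhibitor gene Cdkn1c, 5.22-fold higher (4.91 to 5.55), and the cyclin gene Ccnd1, 6.84-fold lower (6.38 to 7.35). The hexokinase gene Hk2 was 11.4-fold (10.5 to 12.3) and the glucose transporter gene Slc2a1 5.78-fold (5.47 to 6.11) higher within a glycolysis list of 3 higher and 3 lower of 12 (median -0.17). Proliferation had 1 of 12 higher and 0 lower (median -0.45), and the immediate early response 0 of 15 and 2 (median 0.07).

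**Figure D3:**
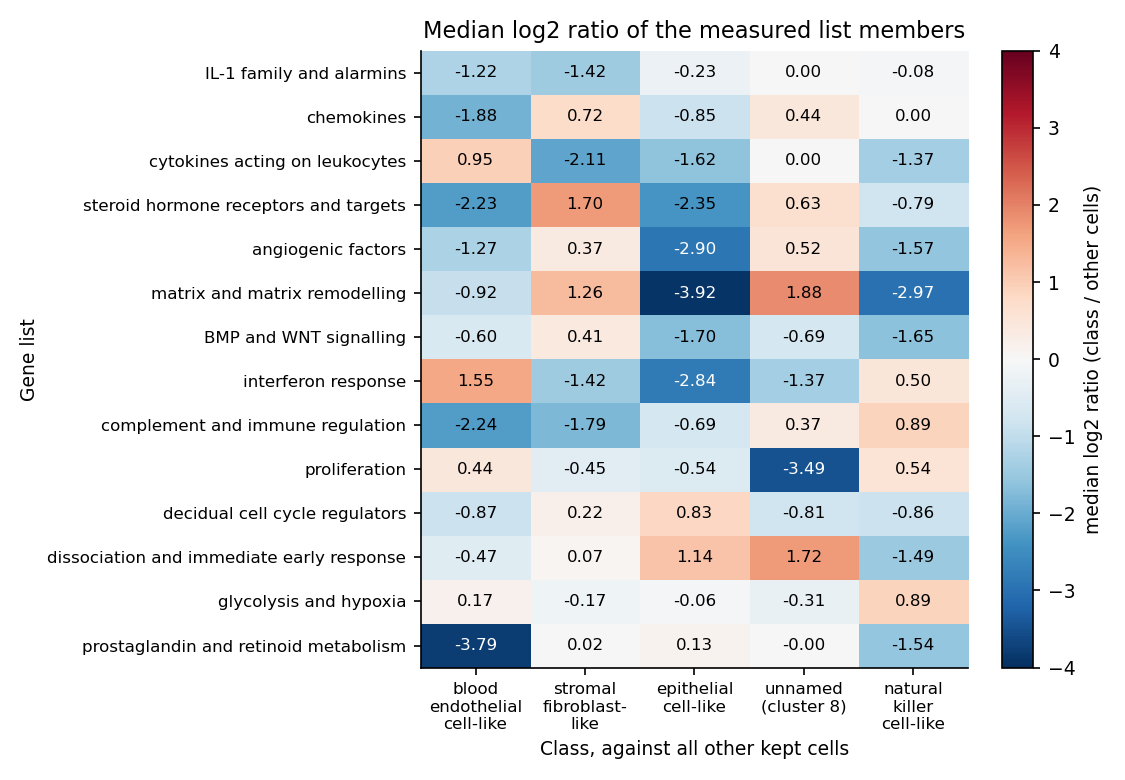
Median log2 ratio of the measured members of each readout list (vertical axis) in each class against the other kept cells (horizontal axis); red is higher in the class and blue lower, and each tile prints its median. The highest median is the matrix list in unnamed cluster 8 (1.88) and the lowest the matrix list in epithelial-like cells (-3.92).

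In epithelial-like cells the immediate early and decidual cell cycle lists had the highest medians, the former also being raised in cluster 8, and the matrix, angiogenic and interferon response lists the lowest. Of the 189 measured genes, 39 were higher and 91 lower. Cyp26a1, which degrades retinoic acid, stood at 331 CPM against 0.120 in the other cells. Hbegf, a growth factor of the EGF family, was 45.1-fold higher (42.3 to 48.2), the vasoactive peptide genes Adm and Edn1 53.1-fold (46.9 to 60.1) and 13.7-fold (12.3 to 15.2), and C3 14.4-fold (13.4 to 15.5). The alarmin gene Il1a had 103 UMIs in this class and 1 in all other kept cells. The immediate early list had 10 of 15 higher and 0 lower (median log2 ratio 1.14, percentile 100), including Atf3 at 6.38-fold (6.19 to 6.57), and decidual cell cycle regulators had 5 of 10 higher and 2 lower (median 0.83). The matrix list had 0 of 26 higher and 22 lower (median -3.92), with the matricellular gene Sparc 30.1-fold lower (27.1 to 33.6) and Col4a1 23.9-fold lower (19.1 to 30.5). Angiogenic factors had 3 of 16 higher and 10 lower (median -2.90), the interferon response 0 of 10 and 9 (median -2.84), steroid hormone receptors and targets 2 of 12 and 7 (median -2.35), BMP and WNT signalling 2 of 17 and 9 (median -1.70) and cytokines 1 of 11 and 7 (median -1.62). Of 13 chemokines 3 were higher, Cxcl16 at 41.1-fold (32.4 to 52.6), and 6 were lower (median -0.85). Complement had 3 of 16 higher and 7 lower (median -0.69), prostaglandin and retinoid metabolism 5 of 10 and 4 (median 0.13), the IL-1 family 3 of 9 and 4 (median -0.23), glycolysis 2 of 12 and 2 (median -0.06) and proliferation 0 of 12 and 2 (median -0.54). The median log2 ratio of all measured genes was itself -0.23 in this class and -0.25 in the natural killer cell-like class. Prap1 (ENSMUSG00000025467; chromosome 7, 140093395 to 140097200), a secreted proline-rich protein gene, took 53259 CPM here.

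In cluster 8 the matrix and immediate early lists had the highest medians and the proliferation list the lowest. Of the 189 measured genes, 68 were higher and 53 lower. The matrix list had 17 of 26 higher and 0 lower (median log2 ratio 1.88, percentile 100), with the collagen genes Col6a3 at 16.9-fold (15.3 to 18.6) and Col5a1 at 12.1-fold (10.5 to 13.8) and the crosslinking enzyme gene Lox at 12.5-fold (10.3 to 15). Hpgd was 232-fold higher (179 to 302). Complement and immune regulation had 7 of 16 higher and 2 lower (median 0.37), with C3 at 49.7-fold (46.1 to 53.5) and C4b at 22.5-fold (16.0 to 31.0). The androgen receptor gene Ar was 9.46-fold (8.09 to 11) and the chemokine gene Cxcl12 18.3-fold (15.8 to 21.2) higher. The immediate early list had 11 of 15 higher and 0 lower (median 1.72), with Egr1 at 5.42-fold (5.16 to 5.69). The proliferation list had 0 of 12 higher and 11 lower (median -3.49), with Top2a, a mitotic topoisomerase, 14.5-fold lower (7.62 to 31.7), and the interferon response 1 of 10 and 8 (median -1.37). Of the remaining lists, angiogenic factors had 6 of 16 higher and 4 lower (median 0.52; Thbs1 19.7-fold higher, 16.9 to 22.9), steroid hormone receptors and targets 5 of 12 and 1 (median 0.63), chemokines 5 of 13 and 3 (median 0.44), and BMP and WNT signalling 3 of 17 and 8 (median -0.69). The IL-1 family had 3 of 9 and 1, cytokines 3 of 11 and 3, decidual cell cycle regulators 2 of 10 and 5, glycolysis 2 of 12 and 5, and prostaglandin and retinoid metabolism 3 of 10 and 2. The cell cycle inhibitor gene Cdkn1a was 4.90-fold higher (4.16 to 5.73), but 0.894-fold with 15 principal components, where Hpgd was 4.90-fold and C3 1.25-fold higher, and the complement median was -0.51 when each cell counted equally. The 9 cells with at least 3 mesothelial markers held 211 of the 231 Hpgd and 968 of the 1129 C3 UMIs of this cluster. Under 9 settings no unnamed class held most cells of cluster 8, so this class has no value there.

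In natural killer cell-like cells, with other leukocytes in the same cluster, the complement and immune regulation and glycolysis lists had the highest medians, and the matrix, BMP and WNT signalling and angiogenic lists the lowest. These sums rest on few cells: the 14 of the 43 with at least 30000 UMIs held 92.5% of the UMIs, and 15 cells had under 2000. With each cell counted equally the glycolysis median was 0.14. Of the 189 measured genes, 29 were higher and 95 lower. Complement and immune regulation had 7 of 16 higher and 3 lower (median log2 ratio 0.89), led by Cd74, the invariant chain of class II molecules, at 600-fold (457 to 801), and the class II gene H2-Aa at 376-fold (199 to 784); with at least 5000 UMIs per cell, a limit added after seeing the data, these were 83.0-fold and 10.1-fold. Il1b, an inflammatory cytokine gene, stood at 192 CPM, with 1 UMI in all other kept cells. Glycolysis had 6 of 12 higher and 2 lower (median 0.89; Eno1 2.75-fold, 2.56 to 2.95), and the interferon response 5 of 10 and 1 (median 0.50; Ifit3 4.51-fold, 3.35 to 5.96). The chemokine gene Cxcl10 was 7.18-fold (6.27 to 8.19) and the lymphoid regulator gene Id2 8.48-fold (7.82 to 9.19) higher. The matrix list had 0 of 26 higher and 25 lower (median -2.97), BMP and WNT signalling 1 of 17 and 13 (median -1.65; Id1 20.0-fold lower, 12.2 to 35.8), angiogenic factors 0 of 16 and 12 (median -1.57) and the immediate early response 0 of 15 and 10 (median -1.49). Chemokines had 4 of 13 higher and 4 lower (median 0.00), and proliferation 0 of 12 and 0 (median 0.54). The IL-1 family had 3 of 9 higher and 2 lower, cytokines 1 of 11 and 7, steroid hormone receptors and targets 0 of 12 and 5, decidual cell cycle regulators 1 of 10 and 5, and prostaglandin and retinoid metabolism 1 of 10 and 6. The median depth of this class was 4547 UMIs. B cells and macrophages, of which it held some, express Cd74 and H2-Aa. These levels, and that of Il1b, need therefore not come from natural killer cells.

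**Figure D4:**
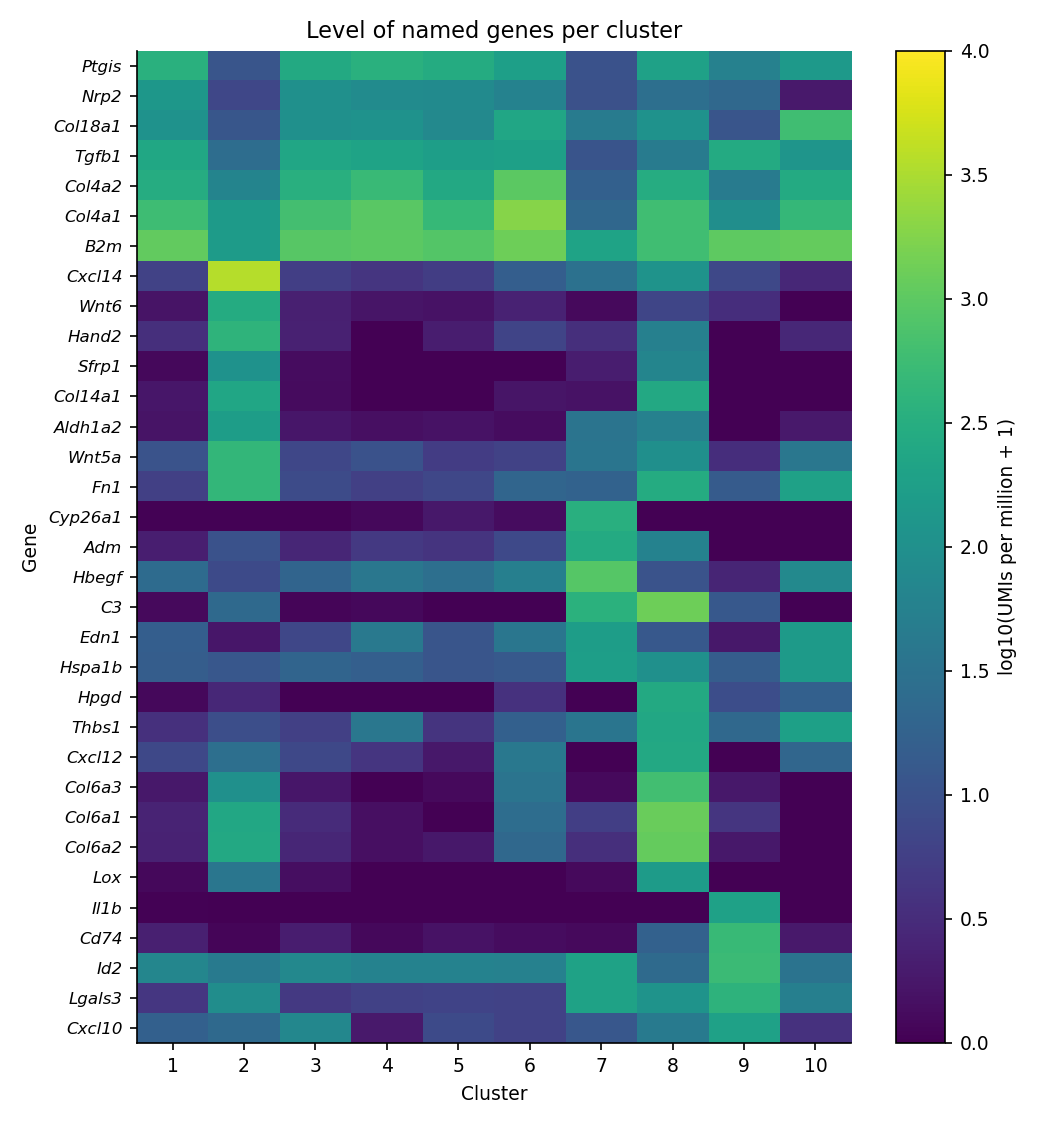
Level of 33 named genes (vertical axis) in each of the 10 clusters (horizontal axis), coloured by log10 of CPM plus a pseudocount of 1. Cxcl14 is highest in cluster 2 at 3619 CPM, C3 in cluster 8 at 1324 and Cyp26a1 in cluster 7 at 331.

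Among the blood endothelial-like clusters, compared with the other endothelial-like cells, the proliferation and matrix lists differed. Cell cycle genes outside the readout lists could still shape the clusters, and genes such as Nusap1, Ube2c and Aurkb led cluster 3. The proliferation differences can therefore restate how the cells were divided. In cluster 3 (289 cells, 17.0% of kept cells), 12 of 12 proliferation genes were higher (median log2 ratio 2.09), with Top2a at 15.4-fold (14.3 to 16.6). In cluster 5 (105 cells, 6.19%) 3 were higher and 3 lower (median -0.56): the mitotic cyclin gene Ccnb2 was 4.29-fold higher (4.02 to 4.58) and Top2a 3.94-fold lower (3.39 to 4.61), and 8 of 26 matrix genes were lower and 0 higher (median -0.66). In cluster 1 (467 cells, 27.5%), led by Mafb, Slfn5 and Nrp2, 11 of 12 proliferation genes were lower (median -2.62). In cluster 4 (132 cells, 7.78%), led by the renin gene Ren1 and by Ramp3, a subunit of adrenomedullin receptors, 9 were lower (median -2.03). Cluster 6 (87 cells, 5.13%) had 11 of 26 matrix genes higher and 0 lower (median 0.95), including Timp3 at 3.43-fold (3.19 to 3.70) and Col4a1 at 2.94-fold (2.85 to 3.03), had 9 of 12 proliferation genes lower (median -1.47), and was led by the tip cell gene Esm1. Its leading genes also included the pericyte marker Rgs5, at 365 against 13.4 CPM in all other kept cells, and 3 of 9 stromal fibroblast markers were detected, Col1a1 at 123, Col3a1 at 75.4 and Col1a2 at 60.8 CPM. Its interferon-response gene Rsad2 was 7.76-fold (6.87 to 8.75) and the BMP target gene Id1 3.39-fold (3.18 to 3.62) higher, and 6 of its cells had at least 3 pericyte markers beside a median of 4398 CPM of endothelial markers. Cluster 10 (27 cells, 1.59%) was led by Bmx, Gja5 and Gja4, genes known from arterial endothelium, and its leading genes also included the smooth muscle marker Acta2, at 379 against 12.5 CPM in all other kept cells. It had Nr2f2, a vein-specifying transcription factor gene, 46.4-fold lower (23.5 to 108), Fn1 28.6-fold (23.8 to 34.3) and Edn1 9.74-fold (8.18 to 11.6) higher, and 2 of 15 immediate early genes higher and 7 lower (median -0.79). Il33 stood at 4.25 CPM (3.27 to 5.44) in cluster 1 and 3.37 (2.47 to 4.48) in cluster 3. The 10 Il33 UMIs of cluster 4 had 7 in 1 cell, and the 6 of cluster 6 were all in 1 cell.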

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

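Signals in barcodes outside the kept cells are given here; the tests of free RNA for the granzymes and of 1 mixture alike in every barcode, the numbers of barcodes that full separation and no relation would give, and the sums over granzymes, over macrophage genes without Tyrobp and Fcer1g, and over Prss29, Spink1 and Ltf, were chosen only after the results were seen. In the 296 barcodes under the gene or UMI minimum (198646 UMIs, median 641 per barcode), the genes of most leukocyte lists stood above their level in the kept cells, but mast cell markers had 0 UMIs (0 to 18.6 CPM) against 28.8 in kept cells. That list includes Kit, its only member with UMIs in endothelial-like clusters 5 and 10, so its level in kept cells need not come from mast cells. Those clusters held 64 and 11 of the list's 2018 UMIs in kept cells, which does not settle the source of the rest. Granzymes, the cytotoxic proteases of natural killer and T cells, reached 54288 CPM, 57.5 times the level of 944 in kept cells. Most kept cells were endothelial-like or stromal, and in cluster 9 alone Gzmd stood at 14654, Gzmc at 8549 and Gzmf at 7425 CPM. The ratio to all kept cells therefore does not show a level above that of natural killer cell-like cells. With no filter the natural killer cell-like share was 14.6%. Natural killer cell markers reached 8659 (kept cells 215) and macrophage or monocyte markers 6464 (kept cells 94.4), or 2764 (kept cells 30.4) without Tyrobp and Fcer1g, which natural killer cells also express. T cell markers stood at 146 (kept cells 4.30), neutrophil markers at 181 (1.37), group 2 innate lymphoid markers at 222 (75.5), B cell markers at 80.5 (11.2) and dendritic cell markers at 55.4 (10.8). These levels rest on few UMIs, in the same order 29, 36, 44, 16 and 11 over the 296 barcodes. Barcodes with at least 3 such UMIs numbered 1, 3, 1, 0 and 0. The genes with the highest ratios included the chemokine genes Ccl3 and Ccl4, the class II gene H2-Aa and the complement gene C1qa. Il33 had 0 UMIs there (0 to 18.6 CPM).

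The excess of leukocyte transcripts in these barcodes over the level in all kept cells was set against 3 explanations. Free RNA spread over all droplets was argued against: an endothelial-like cell held 0.186 granzyme UMIs against 36.4 per barcode under the minimum, a ratio of 0.00511 with an upper bound of 0.00586. For separate low-RNA leukocytes, only full separation of granzymes and macrophage genes into different barcodes was argued against. Barcodes with at least 3 UMIs of both numbered 68 against 84.3 from independent draws, a ratio of 0.807 (0.643 to 0.990). Full separation of the 246 barcodes with granzymes and the 85 with macrophage genes would give 35 (0.415), and no relation between them 70.6. The 6 barcodes with at least 10 macrophage UMIs still held 8900 granzyme CPM, so such barcodes can count for both. Separate leukocytes that held some RNA of others could therefore not be decided on by this count. A single mixture of leukocyte RNA alike in every barcode was argued against, since the granzyme share of the UMIs in the 6 barcodes with at least 10 macrophage UMIs was 0.135 times (0.0389 to 0.25, barcodes resampled) that in the 159 with 0 macrophage UMIs. Debris and leukocytes that also held RNA of others stay open, and no biological explanation was tested, since the design has no groups to test one.

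In the 128 barcodes over the mitochondrial limit (306546 UMIs), pericyte markers stood at 359 CPM against 41.5 in kept cells, with 90 of the 110 UMIs in 1 barcode. Prss29, an implantation protease gene, Spink1 and the lactoferrin gene Ltf together stood at 2326 CPM against 7.04 in kept cells, with all 713 UMIs in 1 barcode.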

How the results depend on the processing

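The thinning to 20000 UMIs per cell and the minimum of 5000 UMIs per cell were chosen only after the data were seen. The ratio of Il33 in stromal to endothelial-like cells ranged from 2.74 to 2.88 over the alternatives that gave it, and the counts of higher and lower readout genes stayed within 1.5 times of the reported ones in 120 of 120 cases. The Il33 levels of the small classes, from few UMIs, moved more. The epithelial-like level ranged from 0.291 to 0.561 CPM (reported 0.558), and the natural killer cell-like level from 0.194 to 1.63 CPM (reported 0.780). The natural killer cell-like share with an Il33 UMI ranged from 0% to 10% (reported 2.33%). The stromal share moved from 25.7% to 29% with a mitochondrial limit of 10%, 28.3% with at least 1000 genes and 2000 UMIs, 29.2% with doublets kept, 28.9% and 28.4% at resolutions 0.25 and 1, 28.8% with 4000 variable genes, 28.3% with readout genes allowed and 29% with at least 5000 UMIs. In these settings most or all cells of cluster 8 joined the stromal class, and with no filter all 55 did, at a stromal share of 24.2%. No unnamed class held most of them in these 9 settings, so it has no value there. With no filter another cluster of 114 cells (5.39%, median 1562 UMIs) stayed unnamed. The natural killer cell-like share was 1.14% with at least 1000 genes and 2000 UMIs, where 15 of the 43 cells of cluster 9 were not kept and 9 fell in the endothelial-like class. It was 1.21% with at least 5000 UMIs, where 23 were not kept and 1 fell in that class. It was 14.6% with no filter, where the endothelial-like share was 53.2% and 2114 cells were kept; 1655 cells were kept with at least 5000 UMIs. With 15 principal components a separate mesothelial-like class of 9 cells formed, and 41 of the 55 cells of cluster 8 were in the unnamed class. The unnamed class then held 2.42% of cells and 0 Il33 UMIs (0% of cells), and its Cdkn1a ratio was 0.894. The cause was not tested. The complement list in endothelial-like cells had a median of 1.00 with at least 1000 genes and 2000 UMIs, where 9 cells of cluster 9 were in that class. In the unnamed class the complement list had a median of -0.51 with means over cells. The causes were not tested. Depth sets the share of cells with an Il33 UMI: thinned to 20000 UMIs it was 13.7% in stromal and 5.54% in endothelial-like cells, at 5000 it was 3.70% and 1.73%, and at 2000 it was 2.07% and 1.09%. At 5000 UMIs it was 0% in epithelial-like, unnamed and natural killer cell-like cells, and at 2000 it was 0% in epithelial-like and natural killer cell-like cells. Cells under each depth were left out, 169 of the endothelial-like cells at 20000 UMIs. The natural killer cell-like values rest on 20 cells at 5000 UMIs (0 to 16.8) and 28 at 2000 (0 to 12.3). Of 840 list medians under alternatives, 805 stayed within 1.5-fold, 33 moved and 2 turned. Of 1782 gene ratios, 1350 stayed within their 95% interval, 431 moved out of it and 1 turned; the median move of these 432 was 1.41-fold, and 119 of all moved more than 2-fold. The largest move was 47.2-fold, for Hpgd in the unnamed class with 15 principal components. No paired analysis was possible because there was 1 library per tissue and no test was run.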

Other observations

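The comparison of clusters 2 and 8, with and without the cells of mesothelial markers, the subclusters of cluster 2, and the tests of free RNA for Il33, reporter features and depth below were chosen only after the results were seen. Both clusters 2 and 8 had stromal fibroblast markers, and their readout genes were far apart. Of 189 measured genes, 42 were higher and 77 lower in cluster 2. Cluster 2 was higher in 11 of 12 proliferation genes and lower in 0 (median log2 ratio 3.19), with Rrm2, a subunit of ribonucleotide reductase, at 95.0-fold (40.7 to 293). It was also higher in Wnt6, 48.3-fold (20.7 to 149), Cxcl14, 32.1-fold (26.3 to 39.7), Slc2a1, 20.0-fold (10.5 to 43.8), and Hand2, 7.32-fold (5.50 to 9.97). Cluster 8 was higher in 19 of 26 matrix genes, seen as a median of -2.05 for cluster 2, in 10 of 16 complement genes (-2.00) and in 10 of 15 immediate early genes (-1.66). Against cluster 8, Hpgd was 151-fold lower in cluster 2 (108 to 215), C3 59.2-fold (53.3 to 65.8), Thbs1 30.5-fold (25 to 37.2) and Cxcl12 9.38-fold (8.02 to 10.9). Cluster 8 was mixed: its 9 cells with at least 3 mesothelial markers held 211 of its 231 Hpgd and 968 of its 1129 C3 UMIs. Without them cluster 8 was higher than cluster 2 by 15.8-fold in Hpgd (8.79 to 27.5), 10.2-fold in C3 (8.49 to 12.2), 36.6-fold in Thbs1 (30 to 44.7) and 11.2-fold in Cxcl12 (9.60 to 13.1). Immediate early transcripts made up 7786 CPM in cluster 2 and 21779 in cluster 8.

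Cluster 2 divided into 3 subclusters. Subcluster a (179 cells), led by Mt4, Dmkn, S100a4 and Clu, was lower in 9 of 13 chemokines and higher in 0 (median -2.29), had 8 of 12 proliferation genes lower (median -1.35), and had Mmp2 3.80-fold lower (3.36 to 4.31) than the other cells of cluster 2. Subcluster b (145 cells), led by Cebpd, Mmp2 and Igfbp3, had Mmp2 3.22-fold (2.94 to 3.52), Sfrp1 2.41-fold (2.23 to 2.61) and Fn1 2.19-fold (2.11 to 2.28) higher, and 9 of 12 proliferation genes lower (median -1.81). Subcluster c (112 cells) had 9 of 12 proliferation genes higher (median 2.34), with Top2a at 22.4-fold (19.7 to 25.5). Its leading genes included the cell cycle genes Prc1 and Aurkb, which the clustering could use, so this can restate how the cells were divided. The Il33 level was 16.6 CPM (13.7 to 19.8) in subcluster b, 8.16 (6.18 to 10.6) in subcluster c and 5.08 (3.73 to 6.75) in subcluster a. In a separate case, 1 of the kept cells held 512 UMIs of the lymphatic chemokine gene Ccl21a, which was found in 5 cells.

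Few of the sorted cells held an Il33 UMI. Sampling at this depth from 1 equal Il33 level per class was argued against as the whole cause. Of the 1697 kept cells, 200 held an Il33 UMI against 304 from Poisson sampling, a ratio of 0.659. At least 3 UMIs were held by 34 cells against 8.89. Such sampling also leaves most cells without an Il33 UMI, so this does not argue against depth as the main reason. Free RNA shared by all droplets as the whole cause was argued against, since the Il33 UMIs per cell were 14.3 times as many in stromal as in epithelial-like cells, with a lower bound of 3.92; for endothelial-like cells the lower bound was 0.948. It stays open that transcripts of the reporter allele lie outside the counted features, since 0 reporter features were among those counted. Uneven Il33 levels between cells of a class may contribute, and no biological explanation was tested, since the design has no groups.

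The Il33 level of subcluster b was 2.59 times that of the other cells of cluster 2 (1.97 to 3.40), and 31.0% of its cells (23.6 to 39.2) held an Il33 UMI against 16.5% (12.4 to 21.3), beside 3.57% of epithelial-like cells at a median depth of 56072 UMIs. Subcluster b was taken because its Il33 level was the highest among the subclusters, which favours ratios above 1. Depth as the whole cause was argued against by the median depths: 48059 UMIs in subcluster b, below the 51445 of subcluster a and the 59050.5 of subcluster c. With cells thinned to 20000 UMIs the ratio was 1.89 (1.20 to 2.99), which does not decide alone, given that choice. The dissociation response stays open: immediate early transcripts stood at 10604 CPM in subcluster b against 6538, and the ratio within 4 equal groups of cells ordered by that share was 2.2 (1.69 to 2.87). Its lower bound passed the limit set in advance only through the lower groups, with 16 and 18 cells of subcluster b and ratios of 4.84 and 5.28; without these it was 1.46 (1.02 to 2.09). No biological explanation was tested, and Il33 UMIs concentrated in few cells make these intervals too narrow.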
